A study of Homo sapiens with 4 samples.

How the data were processed

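Total RNA of cells labelled MKN-45, an established human gastric cancer line, was sequenced. The cells had been infected with a lentivirus meant to raise the transcription factor SIX2 or with a control lentivirus, then selected with puromycin. There were 4 libraries, 2 per group, and the sample titles number them 1 and 2 within each group. Per the labels' protocols, libraries were made from Trizol-extracted RNA with an Illumina TruSeq RNA kit and sequenced on a NovaSeq 6000. The aligner, the counting program and the strand setting are not given in the sources used here. The design text speaks of 2 repeats and the treatment protocol of triplicates, and 4 libraries were analysed here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries. In the group test that spread includes the large difference between numbers described below. The spread within a number may be technical.

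Each deposited file held 1 library as whole-number counts per Ensembl gene, not normalized, per the file headers and the values. All files listed the same 58735 genes. The submitters' processing notes name the mouse build mm9, but all 58735 gene identifiers were found in the human GENCODE release 29 annotation (GRCh38), 58690 of them with the same coordinates. Coordinates are therefore given as in the files, on GRCh38. Without a known strand setting, reads of overlapping antisense genes cannot be told apart, and genes with near-identical copies (paralogs, pseudogenes) are uncertain.

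Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 16343 genes, and libraries were scaled by TMM factors. CPM are counts per 1000000 of the scaled library size. The libraries labelled SIX2 overexpression were compared with controls by edgeR's quasi-likelihood test with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the F statistic. For levels, mean ± SD of the CPM is given with n = 2. Intervals on SIX2 counts are exact Poisson (each library) or binomial (ratios) at 95%, and cover counting error only. Where all libraries of one side had 0 counts, folds are lower bounds against a floor of 3 counts over both libraries.

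The tests and the rule for naming genes were fixed before the data were examined. The rule named SIX2; the 12 protein-coding genes with the largest change in each direction among those past the threshold, with a mean CPM of 5 or more and no overlap between groups; the 5 in each direction with a mean CPM of 50 or more; and up to 4 members of each described list with the smallest adjusted p, or members given as values only where fewer than 2 passed. In the group comparison the parts of the rule that need a called gene named 0 genes. Some genes that the rule covers are not reported here. The comparison of the libraries numbered 2 with those numbered 1 was added after the data were seen, because the libraries split by number. It used the same test and the same naming rule, with number in place of group.

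There were 40 gene lists, also fixed in advance, covering pathways, gastric and intestinal lineage, RNA quality and markers of other cell types. Lists with at least 5 tested members (37) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Lists of intestinal epithelial genes, immune cell markers and endothelial markers had 4, 2 and 3 tested members and were not tested. Within a number there is 1 library per group and no replicate check, so a list's median change was placed among 10000 random lists of the same size matched on mean expression. Random lists do not keep together genes that vary together. A rank beyond all of them can therefore arise without an effect of the label.

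The methods were checked on simulated counts with 200 changed genes. With the observed differences between numbers kept, the group test without a number term recovered 0% of genes changed 1.5-fold, 2-fold or 4-fold, over 16000 genes. With number as a term it recovered 40.3%, 65.7% and 84.8%, with 3 false calls. DESeq2 without a number term recovered 0%, 4.48% and 62.1% over 16343 genes, with 0 false calls, and limma-voom without it 0% at each size. Without differences between numbers, the group test recovered 46.3%, 74.6% and 83.3% over 15468 genes, with 12 false calls. The comparison of numbers recovered 46.3%, 76.1% and 92.4% over 15927 genes, with 13 false calls. For gene lists, camera with an estimated correlation missed a simulated list raised 1.5-fold (adjusted p = 0.120), which the preset correlation called. Neither called any of 30 unchanged lists. Genes were simulated independently, so false calls from genes that vary together could not appear in this check.

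Alternatives covered DESeq2 size factors, upper-quartile scaling and no scaling factors; no filter and a mean CPM of 1 or more; protein-coding genes alone; number as a block; each library left out; DESeq2 1.42.0 and limma-voom; and the newer and robust forms of the quasi-likelihood test. Alternatives on FPKM were not run, because only counts were used here. The depth was 14792869 to 16777792 counts per library, and 3 counts in a library correspond to 0.179 to 0.200 CPM.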

Results

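The data were RNA-seq counts of 4 libraries labelled as MKN-45 cells. Of these, 2 carried a control lentivirus and 2 were labelled as overexpressing SIX2, a homeobox transcription factor of kidney progenitors. The identity of the line was not tested here, where only counts were used and no reference profile of MKN-45 was compared. Totals were 14792869 counts in control replicate 1, 16777792 in control replicate 2, 16423035 in SIX2 replicate 1 and 16083302 in SIX2 replicate 2. Between 24396 and 25472 genes had at least 1 count in a library. Mitochondrially encoded genes held 6.19% and 6.29% of the counts in the controls, and 7.03% and 6.58% in the libraries labelled SIX2 overexpression. The design asks which genes change when SIX2 is raised in gastric cancer cells.

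SIX2 itself was not higher in the libraries labelled SIX2 overexpression. The gene (ENSG00000170577, chromosome 2, 45005161 to 45009430, minus strand, GRCh38, overlapped by 0 annotated genes) had 369 and 597 counts in control replicates 1 and 2. It had 379 and 605 counts in SIX2 replicates 1 and 2. The level was 30.2 ± 7.82 CPM (SD, n = 2) in controls and 30.7 ± 10.9 CPM (SD, n = 2) in the libraries labelled SIX2 overexpression. The log2 fold change was 0.02 (SE 0.37, adjusted p = 1.00, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Between libraries with the same number the ratio was 0.933 (95% interval 0.807 to 1.08) in number 1 and 1.07 (0.958 to 1.20) in number 2, and 1.02 (0.931 to 1.11) pooled over both. Between numbers SIX2 did pass the threshold, at 23.8 ± 1.16 CPM in number 1 and 37.0 ± 1.87 CPM in number 2 (SD, n = 2), a log2 change of 0.64 (SE 0.13, adjusted p = 0.00119, edgeR quasi-likelihood test, a comparison added after the data were seen). SIX2 thus did not follow the group label. Directions between groups are drawn between libraries labelled SIX2 overexpression and controls, not between measured high and low SIX2.

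**Figure D1:**
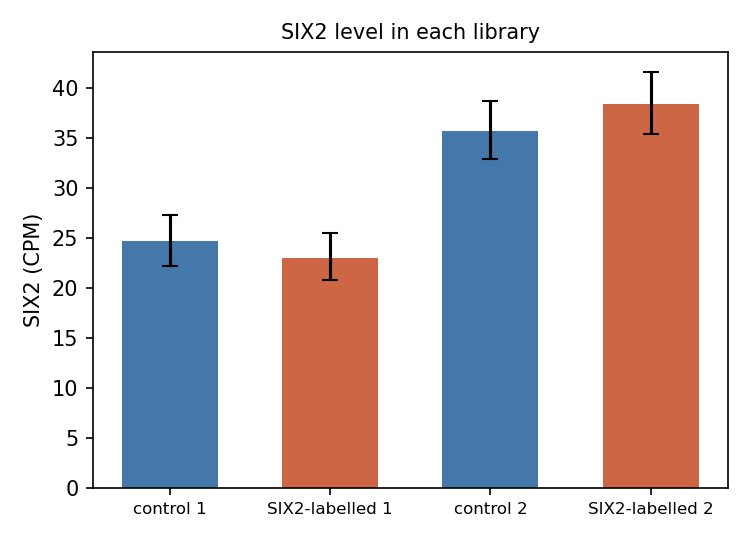
SIX2 level in CPM (vertical axis, from 0) in each of the 4 libraries, with controls in blue and libraries labelled SIX2 overexpression in orange; bars are single libraries and error bars are 95% exact Poisson intervals of the count. The levels were 24.6 and 23.0 CPM in the libraries numbered 1, and 35.7 and 38.3 CPM in those numbered 2.

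Genes related to SIX2 and its partners also lay close between groups. SIX4 was at 14.5 CPM in controls and 12.4 CPM in the libraries labelled SIX2 overexpression, and SIX5 at 11.2 and 12.1 CPM (means, n = 2). The transcriptional cofactor EYA3 was at 47.1 ± 6.41 CPM and 43.6 ± 0.812 CPM (SD, n = 2). Of the 6 tested members of the SIX-EYA-DACH-PAX network, 0 passed the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.726).

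Across the transcriptome, 0 of 16343 genes passed the threshold between the libraries labelled SIX2 overexpression and controls by edgeR's quasi-likelihood test, with 12 genes at an unadjusted p under 0.05. DESeq2 called 0 genes, with 7 at an unadjusted p under 0.05, and limma-voom 0, with 10. In simulated counts with the differences between numbers kept, edgeR and limma-voom recovered 0% of genes changed 4-fold, and DESeq2 62.1%. The absence of called genes therefore does not exclude changes with the label, and the same limit holds for single members of the gene lists. The libraries split by the number in their titles rather than by group. Across genes, log2 CPM of control replicate 1 and SIX2 replicate 1 had a Pearson correlation of 0.991 and those of the pair numbered 2 of 0.987, against 0.916 and 0.917 between replicates of the same group (genes are not independent replicates). The first principal component held 87.9% of the variance and separated the numbers. The biological coefficient of variation was 45.0% with group as the only term and 10.7% with number added.

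**Figure D2:**
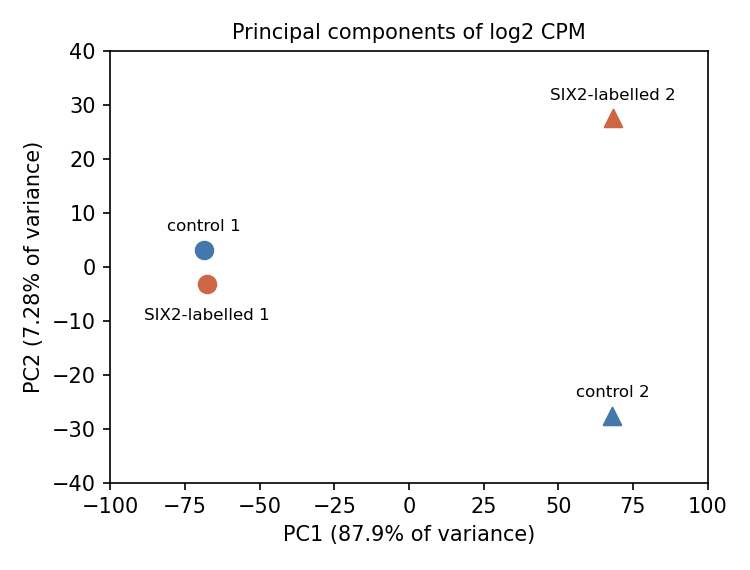
First and second principal components of log2 CPM (axes, with their share of variance) for the 4 libraries; blue marks controls, orange marks libraries labelled SIX2 overexpression, circles are number 1 and triangles number 2. The first component, 87.9% of the variance, separates the numbers, and the second, 7.28%, spreads the pair numbered 2.

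Genes of the type I interferon response were shifted upward as a list, with no single member past the threshold between groups. Of 27 tested members, 0 passed over all genes and 0 adjusted over the list alone, and the median log2 change was 0.10 (camera adjusted p = 0.00121 with the preset correlation; adjusted p = 0.942 with an estimated correlation). The shift lay in number 2: the list's median log2 change was -0.04 between the libraries numbered 1, at the 12.4th percentile of random lists, and 0.50 between those numbered 2, above all 10000 random lists, the highest of which reached 0.27. IFI44, an interferon-induced gene, was at 191 CPM in control replicate 1 and 204 CPM in SIX2 replicate 1, and at 81.5 CPM in control replicate 2 and 187 CPM in SIX2 replicate 2. IFI27 was at 6.34 and 5.58 CPM in number 1, and at 4.37 and 8.43 CPM in number 2. In number 2, 25 of the 27 members were higher in the library labelled SIX2 overexpression, against 11 of 27 in number 1; each number holds 1 library per group, so these values describe the libraries, have no replicate check, and the difference between numbers was not tested. The call depended on the libraries kept: without control replicate 2 the list's direction was opposite, and without SIX2 replicate 1 it was not called. Leaving out 1 library unbalances the numbers, and 13 of these genes were lower and 3 higher in number 2. Such fits mix the difference between numbers with that between groups, here and for the lists below.

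**Figure D3:**
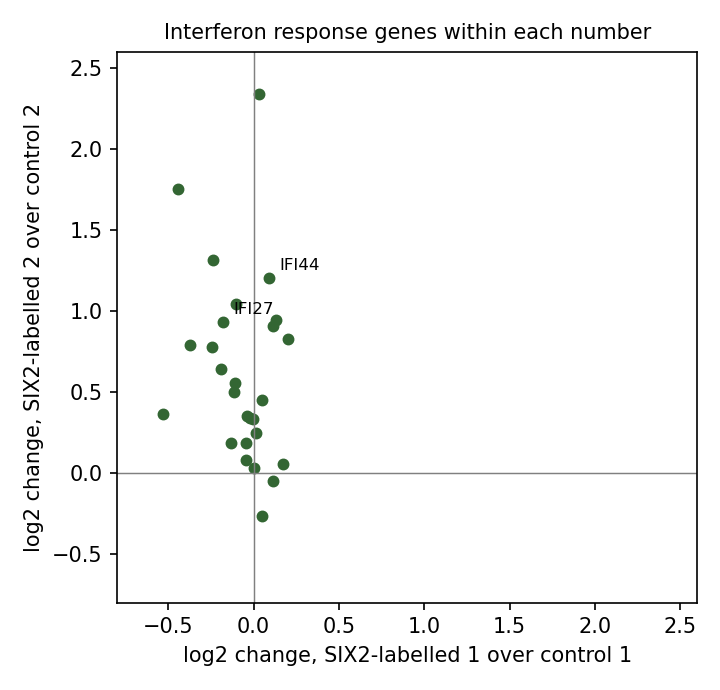
Log2 change of the 27 tested interferon response genes between SIX2 replicate 1 and control replicate 1 (horizontal axis) and between SIX2 replicate 2 and control replicate 2 (vertical axis); each point is a gene. In number 2, 25 genes lie above 0, and in number 1 the values fall on both sides of 0 with a median of -0.04.

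Antigen presentation genes were also shifted upward as a list, with a higher median in number 2 than in number 1. That difference was not tested, and ranks within a number rest on 1 library per group. Their 14 tested members had a median log2 change of 0.15 between groups (camera adjusted p = 0.00497; adjusted p = 0.942 with an estimated correlation), -0.05 within number 1, at the 9.15th percentile of random lists, and 0.43 within number 2, above all 10000. The list kept its call without control replicate 1 and lost it without control replicate 2 (adjusted p = 0.537, in the opposite direction), SIX2 replicate 1 (0.276) or SIX2 replicate 2 (0.0578). B2M, the light chain of class I molecules, was at 1656 and 1692 CPM in control and SIX2 replicates 1, and at 1316 and 2063 CPM in replicates 2. HLA-B, which shares reads with other class I genes, was at 146 and 142 CPM in number 1 and at 99.1 and 178 CPM in number 2. Neither gene passed the test between groups (adjusted p = 1.00 for both, edgeR quasi-likelihood test).

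Of the other lists, 3 passed with the preset correlation. The 15 mitochondrially encoded genes had a median log2 change of 0.11 (camera adjusted p = 0.00525; adjusted p = 0.942 with an estimated correlation), 0.17 within number 1, above all 10000 random lists, and 0.09 within number 2, at the 78.8th percentile. The list lost its call whichever library was left out (adjusted p from 0.0536 to 0.581). Among them MT-CO2 was at 6661 ± 181 CPM in controls and 7972 ± 392 CPM in the libraries labelled SIX2 overexpression (SD, n = 2), and MT-CO1 at 18352 ± 27.8 and 21329 ± 1468 CPM (SD, n = 2). The 29 cytosolic ribosomal protein genes had a median of 0.12 (camera adjusted p = 0.0227; adjusted p = 0.952 with an estimated correlation), but -0.10 within number 1 and 0.29 within number 2, so the sign differed between numbers. These medians lay below all 10000 random lists in number 1 and above all in number 2, so a single pair reached either extreme. Without SIX2 replicate 2 the list was called in the opposite direction (adjusted p = 0.00982), and without control replicate 1 it was not called (adjusted p = 0.627). Changes also followed gene length in opposite directions in the pairs: across 10036 genes, Spearman correlations of the change with length were 0.28 in number 1 and -0.51 in number 2 (genes are not independent replicates), and the shortest genes had median log2 changes of -0.04 and 0.15. RPS6 was at 757 ± 31.5 and 859 ± 100.4 CPM, and RPLP2 at 304 ± 71.0 and 354 ± 9.28 CPM (SD, n = 2). The 6 tested markers of the HEK293 packaging line and neural-type cells had a median of 0.14 (camera adjusted p = 0.0263; adjusted p = 0.942 with an estimated correlation), 0.18 within number 1 and 0.27 within number 2, at the 97.1st and 96.1st percentiles of random lists. It lost its call whichever library was left out (adjusted p from 0.0578 to 0.583). In that list the tubulin gene TUBB3 was at 0.739 ± 0.478 and 1.64 ± 0.0943 CPM, and VIM, also expressed by mesenchymal cells, at 281 ± 80.8 and 369 ± 175 CPM (SD, n = 2). In these 5 lists 0 members passed the threshold, over all genes or adjusted over the list alone, and fry called 0 of the 37 lists. With number as a term, 1 interferon member was higher over all genes and 5 adjusted over the list alone, and the other 4 lists had 0.

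Lists linked to stemness, WNT signalling and epithelial-mesenchymal transition did not pass the test between groups. The 12 pluripotency and stemness genes had a camera adjusted p of 0.375, the 15 WNT/beta-catenin targets 0.726 and the 16 mesenchymal genes 0.136, each with 0 members past the threshold over all genes and 0 adjusted over the list alone. KLF4 was at 66.3 ± 9.81 CPM in controls and 79.0 ± 9.44 CPM in the libraries labelled SIX2 overexpression, and CD24 at 165 ± 11.2 and 192 ± 35.6 CPM. The WNT target RNF43 was at 2.01 ± 0.111 and 2.92 ± 0.528 CPM, and TCF7 at 1.27 ± 0.481 and 0.811 ± 0.288 CPM. S100A4 was at 394 ± 0.172 and 460 ± 114 CPM (SD, n = 2 throughout). The lowest camera adjusted p among the other lists was 0.106, for extracellular matrix and matrix protease genes. With number as a term, 6 more lists passed. Mesenchymal (camera adjusted p = 0.0358), extracellular matrix (0.00788), NF-kB (0.00788) and G2/M genes (0.0493) were shifted toward higher levels in the libraries labelled SIX2 overexpression. Drug efflux transporters (0.0145) and the structural RNAs of the nucleus that serve as a sign of RNA quality (0.00668) were shifted toward lower levels, the latter with a median log2 change of -0.00 and a mean of -0.26 over 5 members, 1 of which, RN7SL2, passed on its own. Of the NF-kB genes 1, CCL5, passed on its own, and of the other 4 lists 0 members did. With an estimated correlation the adjusted p = 0.824 for each of the 6. The mesenchymal, extracellular matrix, NF-kB and drug efflux shifts lay mainly in number 2. Their median log2 changes were 0.03, -0.01, -0.06 and -0.01 within number 1. Within number 2 they were 0.26, 0.29, 0.37 and -0.29. G2/M genes had 0.09 and 0.11, and the structural RNAs -0.06 and -0.10. Each number holds 1 library per group, and these differences between numbers were not tested.

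With number as a term beside group, 8 genes passed the threshold, 6 higher and 2 lower in the libraries labelled SIX2 overexpression. Of the 16343 tested genes 501 had an unadjusted p under 0.05, a smaller share than the 0.05 that unchanged genes would give. DESeq2 with the same terms called 0, with 53 of 30912 genes under 0.05, also a smaller share. The 8 genes are named after their values were seen. The signal recognition particle RNA RN7SL2 fell by 1.25 on the log2 scale (SE 0.18, adjusted p = 6.14e-08) and the mitochondrial transfer RNA MT-TY fell by 0.99 (SE 0.21, adjusted p = 0.0114), both lower in each number. The chemokine CCL5 and IFI44 had log2 changes of 0.72 (SE 0.16, adjusted p = 0.0137) and 0.64 (SE 0.14, adjusted p = 0.0181) by edgeR's quasi-likelihood test. The pairs disagreed: the log2 change was 0.00019 within number 1 and 1.86 within number 2 for CCL5, and 0.091 and 1.20 for IFI44. CCL5 was at 146 CPM in both libraries numbered 1, and at 5.44 and 20.1 CPM in control and SIX2 replicates 2. The other 4 were the pseudogenes GTF2IP1, RPSAP47 and AC024293.1 and the kinase gene SIK1B, all of which have near-identical copies, as does RN7SL2, and are uncertain. The fit had 1 residual degree of freedom per gene, and its p-values rest mainly on a spread pooled over genes. They do not measure how far the pairs of a single gene disagree.

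The largest differences in these comparisons lay between the libraries numbered 2 and those numbered 1, each number holding 1 control and 1 library labelled SIX2 overexpression. The labels give no meaning to the number beyond replicate, and this comparison was added after the data were seen. Its p-values and SDs measure the spread between the control and the SIX2-labelled library of each number. If a number is a single stock of cells, they do not measure variation between stocks. LPL, lipoprotein lipase, was at 372 CPM in both libraries numbered 2 and had 1 count in number 1, a ratio of 11702 (counting interval 2100 to 462259). CGA, the shared subunit of glycoprotein hormones, was at 869 ± 163 CPM in number 2 and 2.10 ± 0.0382 CPM in number 1 (SD, n = 2), 413-fold higher. EREG, a ligand of the EGF receptor, was at 0.866 ± 0.210 CPM in number 2 and 85.4 ± 2.55 CPM in number 1 (SD, n = 2), 99.2-fold higher in number 1. LUM, which encodes the matrix proteoglycan lumican, had 2 counts in number 2 and 1442 in number 1, a ratio of 745 (counting interval 206 to 6158).

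By edgeR's quasi-likelihood test 7151 of 16343 genes passed between numbers, 3622 higher and 3529 lower in number 2, of which 2669 changed at least 2-fold. Among the genes named by the rule, 9 had 0 counts in number 1. They included the metalloprotease gene ADAM12, at least 629-fold higher in number 2 at 59.8 ± 8.33 CPM, and SLFN11, at least 506-fold higher at 48.2 ± 3.98 CPM (SD, n = 2). HS6ST2, LRRN2, CPVL, CACNA2D1, FABP5, UGT1A6 and SDC2 were at least 289, 209, 166, 160, 152, 127 and 108-fold higher; FABP5 has pseudogenes and UGT1A6 shares exons with its family, so both are uncertain. SESN3, PFN2 and AKR1C2 were higher by 9.09 (SE 0.28), 6.89 (SE 0.15) and 5.00 (SE 0.16) on the log2 scale, and MAGEB2 and C19orf38 had 3 and 1 counts in number 1 against 2232 and 911 in number 2. Lower in number 2 were ARSE, with 0 counts there and at least 133-fold higher in number 1, and TOX3, IGSF9B and B4GALNT2, with 1, 2 and 2 counts in number 2 against 430, 491 and 336. UNC13A, C5AR2, DCN and CPA4 had log2 changes of -5.23 (SE 0.18), -5.20 (SE 0.23), -4.95 (SE 0.25) and -4.78 (SE 0.17), and the interferon-induced gene RSAD2 of -5.63 (SE 0.48). The germ cell alkaline phosphatase gene ALPG, which has near-identical relatives, PDZD2 and the collagen receptor subunit ITGA1 had log2 changes of -3.29 (SE 0.13), -3.04 (SE 0.12) and -2.88 (SE 0.12). CCL5 had a log2 change of -3.53 (SE 0.35), with an adjusted p of 4.17e-06 by edgeR, the highest of the 32 genes that the rule named by size of change.

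Inflammatory, immediate early and angiogenic genes were lower in number 2. Of 20 tested NF-kB and inflammatory genes, 18 were lower and 0 higher, over all genes and adjusted over the list alone, with a median log2 change of -2.24 (camera adjusted p = 3.31e-18; adjusted p = 0.447 with an estimated correlation). The cytokine IL6 was at 63.0 ± 0.554 CPM in number 1 and 2.46 ± 1.19 CPM in number 2, ICAM1 at 107 ± 4.69 and 19.1 ± 0.912 CPM, and TNFAIP3 at 111 ± 2.38 and 18.7 ± 2.73 CPM (SD, n = 2). Of 20 immediate early genes, 14 were lower and 2 higher, over all genes and adjusted over the list alone, with a median of -1.13 (camera adjusted p = 4.26e-12; adjusted p = 0.448 with an estimated correlation). SPRY4, FOSL1, DUSP4 and JUN, which are induced by growth factor signalling, had log2 changes of -5.06 (SE 0.22), -2.71 (SE 0.14), -2.24 (SE 0.12) and -2.28 (SE 0.13). Of 13 angiogenic factors, 10 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 7.22e-09; adjusted p = 0.447 with an estimated correlation), among them ANGPTL4 at 45.5 ± 2.40 and 4.24 ± 0.435 CPM and FGF2 at 153 ± 6.46 and 50.1 ± 11.1 CPM (SD, n = 2).

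Oxidative stress, cholesterol and DNA replication genes were higher in number 2. Of 19 tested NRF2 genes, 13 were higher and 1 lower (14 and 1 adjusted over the list alone), with a median log2 change of 0.71 (camera adjusted p = 5.03e-08; adjusted p = 0.447 with an estimated correlation). AKR1C1 and AKR1C2, aldo-keto reductases of nearly the same sequence and so uncertain, had log2 changes of 3.51 (SE 0.22) and 5.00 (SE 0.16), and the cystine transporter gene SLC7A11 was at 86.1 ± 1.96 CPM in number 1 and 216 ± 41.3 CPM in number 2 (SD, n = 2). Of 22 cholesterol biosynthesis genes, 13 were higher and 2 lower (14 and 2 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.99e-04; adjusted p = 0.447 with an estimated correlation). INSIG1, FDFT1 and IDI1 had log2 changes of 2.04 (SE 0.11), 1.38 (SE 0.11) and 1.51 (SE 0.13). Of 22 G1/S and DNA replication genes, 14 were higher and 0 lower, also adjusted over the list alone, with a median of 0.48 (camera adjusted p = 0.00588; adjusted p = 0.448 with an estimated correlation), and POLA1 and MCM6 had log2 changes of 1.01 (SE 0.11) and 0.88 (SE 0.11).

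Fibroblast markers, a check for RNA of another cell type, went both ways between numbers. Of 7 tested, 2 were higher and 3 lower in number 2, over all genes and adjusted over the list alone, with a median log2 change of -0.93 (camera adjusted p = 0.0235; adjusted p = 0.663 with an estimated correlation). LUM and DCN were among the lower genes, COL1A1 was at 55.5 ± 2.01 CPM in number 1 and 277 ± 3.58 CPM in number 2, and FBLN1 was at 532 ± 2.27 and 521 ± 31.1 CPM (SD, n = 2) without passing.

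Receptor tyrosine kinase genes also went both ways between numbers. Of 19 tested, 6 were higher and 10 lower in number 2, over all genes and adjusted over the list alone (camera adjusted p = 5.26e-04; adjusted p = 0.447 with an estimated correlation). Ligands of the EGF receptor family were among the lower genes, with EREG, TGFA and AREG at log2 changes of -6.62 (SE 0.19), -2.36 (SE 0.15) and -2.90 (SE 0.24), and the receptor gene ERBB3 at -1.62 (SE 0.13). By camera with the preset correlation, 17 of 37 lists passed between numbers, and with an estimated correlation 0 did.

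The difference between numbers also varied by chromosome. Over 9672 autosomal genes with a mean CPM of 10 or more, and after removal of trends on GC content and gene length, the median log2 difference of number 2 from number 1 was 0.50 (SE 0.04) for the 323 genes of chromosome 14 and 0.23 (SE 0.06) for the 401 genes of chromosome 10. It was -0.37 (SE 0.06) for the 281 genes of chromosome 20 and -0.32 (SE 0.07) for the 144 genes of chromosome 18. The SD of the medians over the 22 autosomes was 0.207 between numbers, against 0.00730 between the libraries labelled SIX2 overexpression and controls.

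**Figure D4:**
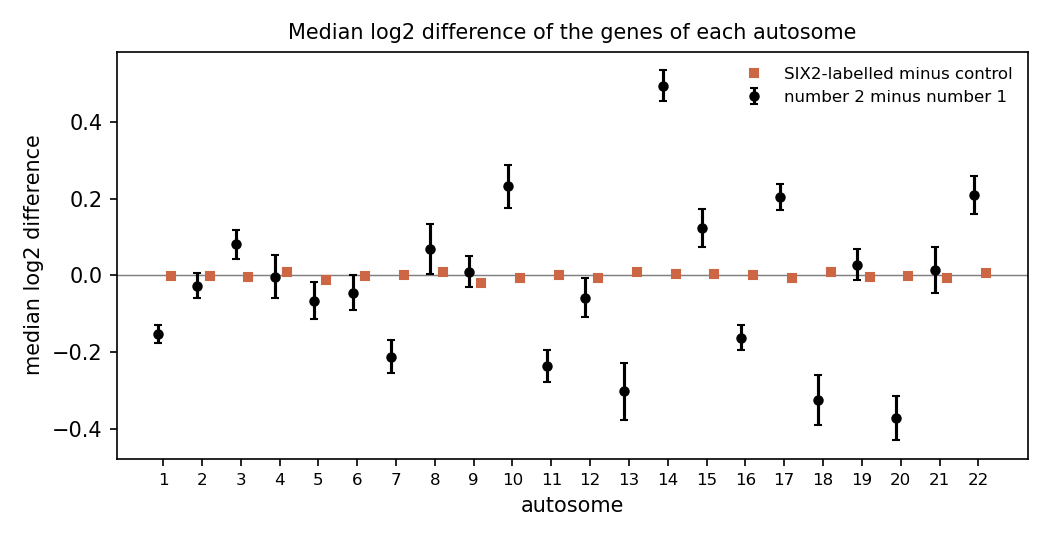
Median log2 difference (vertical axis) of the genes of each autosome (horizontal axis), for number 2 minus number 1 (black points, bars ± 1 SE of the median) and for libraries labelled SIX2 overexpression minus controls (orange squares). Chromosome 14 lies highest between numbers at 0.50 and chromosome 20 lowest at -0.37, while the group medians lie near 0.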

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

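The alternatives with a length correction, DESeq2 with a number term, those of the list p-values and all results of the comparison of numbers were chosen after the data were seen. The count of 0 genes between groups stayed 0 under the scaling, filtering and tool alternatives without a number term. Across these settings 0 to 69 genes had an unadjusted p under 0.05. This is no sign of stability for edgeR and limma-voom, which recovered 0% of simulated genes changed 4-fold without a number term. DESeq2 recovered 62.1% of them. With the replicate block (the number of the titles as a term) edgeR called 8 genes (6 higher, 2 lower, 1 at least 2-fold), and with the block and a gene length correction 21 (15 higher, 6 lower, 2 at least 2-fold), while DESeq2 with the block called 0; the cause was not tested. Same-numbered libraries deviated together, with a correlation of 0.865 over genes, but the labels name no shared batch. SIX2's log2 fold change, at 0.02, was -0.0060 with limma-voom and -0.013 with the block and length correction. With 1 library left out, which unbalances the numbers, it ranged from -0.39 to 0.34. The same fits gave -0.20 to 0.81 for VIM, -0.67 to 0.19 for SIX4 (0.10 without SIX2 replicate 1), -0.24 to 0.040 for EYA3 and -0.056 to 0.45 for S100A4. The 5 lists called by camera became 0 without a filter, with an estimated correlation, with fry, and with the block and an estimated correlation; 11 with the block, with or without the length correction; and 9 to 16 with 1 library left out. Leaving out 1 library moved the adjusted p from 3.86e-14 to 0.581 for interferon genes (0.0488 in the opposite direction without control replicate 2), from 4.08e-05 to 0.537 for antigen presentation genes (0.537 in the opposite direction without control replicate 2), and from 3.36e-06 to 0.627 for ribosomal protein genes (0.00982 in the opposite direction without SIX2 replicate 2). Mitochondrially encoded genes (0.0536 to 0.581) and HEK293 and neural-type markers (0.0578 to 0.583) lost their call whichever library was left out. Among the members named from lists, the block raised IFI44 past the threshold over all genes and changed no other call. Between numbers, the 7151 genes stayed within 1.5 times under every alternative, from 4853 without control replicate 1 to 8416 without control replicate 2. In fits that leave 1 library in a group, that library is assumed to vary like the rest. Those fits also unbalance the numbers, so their list calls and directions between groups mix in the difference between numbers. The 2 alternatives on FPKM were not run. Depth limits genes near the level of 3 counts in a library.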

Other observations

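All tests in this part were chosen after the result was seen, among them those of depth and gene length on the split between numbers, except that of gene length on the interferon genes. The rules for exchanged labels and for an effect of the label common to both numbers were also changed after their values were seen: the earlier rules, which ignored SIX2 between numbers and the single library per group in each number, had excluded both.

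Some genes used to tell cell types apart were picked by hand and are given as counts, without a test. The intestinal transcription factor genes CDX1 and CDX2, the stem cell factor gene SOX2 and the leukocyte gene PTPRC had 0 counts in all 4 libraries. CDH17, an intestinal cadherin, had 70 and 81 counts in control and SIX2 replicates 1, and 0 and 1 in replicates 2. CEACAM5 had 17 and 32 counts in number 1 and 0 in both libraries numbered 2. E-cadherin (CDH1) had 329 and 336 counts in number 1 against 89 and 127 in number 2, and EPCAM lay between 149 and 201 counts. CLDN18 had 37 and 31 counts in control and SIX2 replicates 1 and 81 and 32 in replicates 2, MUC2 lay between 8 and 14 counts and KRT20 between 0 and 4. CEACAM6 had 2 and 3 counts in number 1 and 0 in number 2, and COL1A2 1 count in all. MET, a receptor tyrosine kinase gene, lay between 3334 and 4117 counts in every library, and VIM between 3347 and 7785. In the lists fixed in advance, 19 of 22 gastric epithelial genes found had a mean under 1 CPM of unscaled counts. So did 21 of 24 intestinal epithelial genes. Most listed gastric genes thus lay under 1 CPM in libraries labelled as a gastric cancer line. No reference profile of MKN-45 was compared, so whether either number holds that line was not tested.

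Of the 17 lists that passed between numbers, 9 are described here, with members counted by edgeR's quasi-likelihood test. Of 13 heat shock genes, 8 were lower and 1 higher in number 2 (camera adjusted p = 0.00347; adjusted p = 0.447 with an estimated correlation). Of 18 apoptosis regulators, 10 were lower and 1 higher (camera adjusted p = 0.00359; adjusted p = 0.448 with an estimated correlation). Of 25 HOX genes, 11 were lower and 2 higher (camera adjusted p = 0.0235; adjusted p = 0.448 with an estimated correlation). Of 27 interferon response genes, 13 were lower and 3 higher (camera adjusted p = 0.00347; adjusted p = 0.772 with an estimated correlation), and of 15 epithelial junction and keratin genes 8 were lower and 3 higher (camera adjusted p = 0.0122; adjusted p = 0.448 with an estimated correlation). Higher in number 2 were 12 of 24 G2/M genes, with 2 lower (camera adjusted p = 0.00767; adjusted p = 0.723 with an estimated correlation), and 13 of 29 ribosomal protein genes, with 2 lower (camera adjusted p = 0.00767; adjusted p = 0.817 with an estimated correlation). So were 7 of 11 histone genes, with 1 lower (camera adjusted p = 0.0235; adjusted p = 0.511 with an estimated correlation), and 3 of 6 members of the SIX-EYA-DACH-PAX network, with 1 lower (camera adjusted p = 0.0421; adjusted p = 0.448 with an estimated correlation).

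SIX2 was not higher in the libraries labelled SIX2 overexpression. Depth does not account for it, since the upper 95% limit of the fold between the labelled groups was 1.11. Labels exchanged among the 4 libraries cannot be told apart from this, since the size of rise to look for is not given in the labels. The highest SIX2 level was 1.67 times the lowest. SIX2 passed the threshold between numbers, the grouping that an exchange of control replicate 2 with SIX2 replicate 1 would give. However, 7151 of 16343 genes passed there, so this does not single out SIX2. A construct whose transcripts were not counted at the SIX2 gene, a change at the protein level alone, or an exchange with libraries outside the series was not tested and stays open.

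Libraries with different numbers differed at 7151 genes. With each library's trend on gene length removed 7575 genes were called, so length does not account for the split. Nor does depth, which was already near equal, at 14792869 to 16777792 counts per library. With all libraries thinned to the same total 7117 genes were called, a weak test because thinning changed depth little. Cells of a second type added to one number at under 90% of its RNA would lower no gene 10-fold there, yet among genes with a mean of 20 CPM or more in the higher number, 54 were at least 10-fold higher in number 2 and 19 in number 1 (at 50-fold with the same limit, an earlier and less decisive test, 24 and 2). The spread of the autosomes' medians exceeded every one of 10000 permutations of genes over chromosomes (p = 1e-04, the smallest they can give; SD 0.207 against at most 0.0588), as different chromosome copy numbers would give. A candidate explanation is therefore that the numbers hold cells of different stocks or lines, which no label states; the design names no biological difference between the numbers, and exchanged labels stay open as above.

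Interferon genes were higher in SIX2 replicate 2 than in control replicate 2. A gene length trend was present in that pair, but the list's median stayed at 0.48 (spread 0.149) with the trend removed. RNA carried over from the libraries numbered 1 would need a share of 30.0%, the median over the 12 of 27 members more than 2-fold higher there than in control replicate 2, against an upper 95% limit of 2.30% from 5 genes abundant in number 1 and near 0 in control replicate 2. An effect of the group label common to both numbers cannot be told apart from variation between cultures, since the median was -0.0358 in number 1 but each number holds 1 library per group. An effect present in cells numbered 2 alone was not tested and stays open.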
